A study of Rattus norvegicus with 12 samples.

How the data were processed

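Heart RNA of male Sprague-Dawley rats was depleted of ribosomal RNA and sequenced in 12 libraries, 3 in each of 4 groups (sorafenib or water, 14 or 28 days), per the labels' protocols. The deposited values are read counts per gene. They were made with featureCounts 2.0.1 on a RefSeq annotation of the rat assembly mRatBN7.2, in paired mode and with no strand setting, per the file headers. STAR is named as aligner in the submitters' processing notes, with no version. The library kit marks strand, per the labels, and the counts do not use it, so reads of overlapping and antisense genes cannot be told apart. Exons of 5788 of the 34322 genes overlap those of another gene. Each day has its own table with the same genes. In the table of day 14, 2 columns of counts match no sample and were not used here.

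Groups were taken from the labels. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust dispersion, after filterByExpr and TMM normalization, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Sorafenib was compared with water within each day. A fit of all 4 groups gave the difference between the days, and the water groups were compared over time. SE is the log2 fold change divided by the root of the F statistic. CPM values are TMM-normalized and given as mean ± SD. The average of both days uses the fit of all 4 groups with equal weight per day.

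Before the data were examined, 36 gene lists, the comparisons, the alternatives and a rule for naming genes were fixed. Of the lists, 35 had the minimum of 5 members, since the protein genes of the mitochondrial genome have no counts in the tables (0 of them found). Lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists, then with an estimated correlation and with fry. The rule names, per day, up to 10 genes per direction by fold among genes past the threshold at a mean of 1 CPM or more whose sorafenib libraries all lie on one side of the water libraries and whose symbol is not a locus number. Where none pass it names the 5 of smallest p. For the difference and the water groups it names 5 per direction without the condition on sides. It adds 4 members of smallest p of each list that passes and 13 genes fixed by name. For the average of both days, chosen after the data had been seen, the rule of the days was used with the condition on sides at each day.

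Alternatives were DESeq2 1.42.0, RLE factors, no filter and a stricter filter (1 CPM in 3 libraries), no robust dispersion, a fit of all groups, the number of the title as a block, and each library left out in turn. All alternatives for the average, and removal of each library's trend with gene length (lowess span 0.3), were added after seeing the data.

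Code was tested on simulated counts with 200 changed genes drawn from the real means and library sizes. At day 14, on 17046 genes, it called 71.6% of genes changed 2-fold and 13.4% of those changed 1.5-fold. At day 28, on 16602 genes, it called 52.2% and 5.97%. For the difference, on 17757 genes, it called 11.9% of genes changed 2-fold. For the average, on 17801 genes, it called 71.6%. Changed genes were drawn only from those above 2 CPM on average, so these shares do not cover genes of lower level. Simulated counts took their spread from edgeR's dispersion of each gene. The simulated genes were independent of each other, unlike real ones. Recovery in the real libraries may thus be lower, and these shares do not show how many real changes were missed.

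Chromosome numbers follow the order of the assembly's sequences in the files, and starts and ends are those of the outermost exons. A gene table of another assembly, GRCr8, was used only to check that order: 27234 symbols (79.3%) matched, and 99.8% of those placed in both lay on the same chromosome. Where a whole group has no count of a gene, 3 counts over the group served as the floor. With 1 to 3 counts in a group, the ratio of summed shares carries an exact binomial interval, for counting error only. Shares of single libraries carry 95% Wilson intervals. No replicate pair agreed within sampling noise: the smallest chi-square per gene within a group was 8.075.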

Results

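RNA was sequenced from hearts of male rats that were given sorafenib, an inhibitor of RAF and of several receptor tyrosine kinases used against cancer, or water. Doses of 50 mg per kg were given daily for 14 or 28 days. The series names cardiac toxicity, the splicing factor RBM20, and sarcomeric and mitochondrial genes as its subject. There were 4 groups of 3 libraries, named here by group and replicate number. The labels do not state that every library came from a separate rat, so p-values measure the spread between these libraries. Total counts per library were 13746366 to 18534816 at day 14. At day 28 they were 16785038 to 26403196 in 5 libraries and 1036483 in sorafenib replicate 3. In that library 1 count equals 0.965 CPM, so genes near 1 CPM rest there on single counts. It had counts for 16908 genes, against 21899 to 22748 in the other libraries, and it alone set the first principal component (34.9% of the variance). The ribosomal precursor Rn45s took 1.643% of the counts in it (95% Wilson interval 1.619 to 1.668). That share was 1.255% in sorafenib day 28 replicate 2 (1.25 to 1.26) and 0.8417% in sorafenib day 14 replicate 5 (0.8368 to 0.8465). In no other library did it exceed 0.5374%. The mitochondrial ribosomal RNA mt-Rnr2 took 1.315% in sorafenib day 28 replicate 2 (1.309 to 1.32) and at most 0.2053% elsewhere. These intervals cover counting error only.

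At day 14 no single gene passed the test, and the genes of smallest p are given as such. Among them were higher levels of Fmo2, a flavin-containing monooxygenase, at 206 ± 25.9 CPM with sorafenib against 66.5 ± 21.1 with water (SD, n = 3 each). Oas1k, of the oligoadenylate synthetase family, was at 6.9 ± 1.98 against 1.16 ± 0.235 CPM. Srms, Asb18 and Myo3b had log2 fold changes of 2.78, 1.31 and 1.30. On the lower side, the kinase gene Dyrk2 was at 71.8 ± 9.96 against 160 ± 16.7 CPM, and Nox4, an NADPH oxidase, at 6.84 ± 1.95 against 25.7 ± 8.13 CPM. Sphkap, Inha and the receptor tyrosine kinase gene Kit had log2 fold changes of -1.14, -2.12 and -1.28. The smallest adjusted p of edgeR's quasi-likelihood test was 0.078. Of 17406 genes tested, 0 passed an adjusted p of 0.05, 2440 had an unadjusted p under 0.05 where 870 are expected by chance, and DESeq2 called 393 (218 higher, 175 lower). Leaving out water replicate 2 gave 27 genes and leaving out sorafenib replicate 5 gave 9. A fit of all 4 groups gave 4 and no filter on low counts gave 87. Exons of Srms overlap those of another gene, so its counts are less certain.

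The gene lists fixed beforehand gave the following at day 14. The interferon list lay lower in 34 of 35 genes (median log2 fold change -0.81, camera adjusted p = 4.62e-09), with Irf7 at -1.14 ± 0.21 (SE), Rsad2 at -1.03 ± 0.24, Rtp4 at -0.93 ± 0.23 and Isg15 at -1.61 ± 0.45. The myeloid markers lay lower in 20 of 20 (median -0.74, adjusted p = 5.73e-05), with Cybb, Ctss, C1qb and Csf1r between -1.18 and -0.75. Lower medians also came from cell cycle (-0.31, adjusted p = 0.000338), the output of MAPK signalling (-0.32, 0.00493), heat shock (-0.25, 0.00783), stress of the endoplasmic reticulum (-0.36, 0.0108) and extracellular matrix (-0.14, 0.0117). Inflammation (-0.36) and immediate early genes (-0.19) reached an adjusted p of 0.0497, just inside the threshold. Sorafenib replicate 5 stood apart from the other sorafenib libraries in many of these lists. Relative to the water mean, its mean was -0.24 for interferon, against -0.94 and -1.14 in the others and -0.28 to 0.49 in the water libraries. For the myeloid markers it was -0.15, against -1.24 and -0.82 and a water range of -0.34 to 0.53. It was 0.36 for cell cycle, against -1 and -0.96, and 0.28 for matrix, against -0.58 and -0.38. For inflammation it was 0.33, against -0.74 and -0.43, and for immediate early genes -0.03, against -0.82 and -0.46. Higher medians came from genes of the glucocorticoid response (0.46, adjusted p = 0.00493), genes raised in the stressed myocardium (0.33, 0.0497) and PPAR alpha targets (0.30, 0.0497). Without water replicate 3 or without sorafenib replicate 6 none of the higher calls (0) was left. That water library was at -0.59 for the glucocorticoid list, against 0.26 and 0.33 in the other water libraries. For PPAR alpha targets the water libraries were at 0.48, -0.43 and -0.05 and the sorafenib libraries at 0.17, 0.89 and 0.46, so the ranges overlapped. In the myocardial stress list, Myh7, Nppb and Nppa passed when adjusted over the list alone (adjusted p = 0.0111, 0.0111 and 0.0295) and not over all genes. In the glucocorticoid list, Sult1a1, Zbtb16, Angptl4 and Mt2A did so on the higher side (adjusted p = 0.00525 to 0.0313) and 1 member, Sgk1 (-0.52 ± 0.17), on the lower side. These 12 of 35 calls rest on camera's preset correlation of 0.01. With an estimated correlation 0 lists passed (smallest adjusted p = 0.84), and fry gave 0. Without sorafenib replicate 6 the count was 2, without sorafenib replicate 7 it was 5 and without water replicate 3 it was 7, and 5 of the 10 ways to part the 6 libraries gave 12 lists or more.

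At day 28 no single gene passed either. The smallest p values belonged to Nrep, a regulator of neuronal regeneration, at 23.7 ± 3.82 CPM with sorafenib against 69.4 ± 10.7 with water (SD, n = 3 each), and to Ngdn, at 74.1 ± 7.11 against 28.6 ± 4.21 CPM. Prodh1, proline dehydrogenase, was at 228 ± 41.2 against 82.2 ± 5.79 CPM. Galnt15, Erich6 and Plag1 had log2 fold changes of 1.32, 2.67 and 0.97. On the lower side, the interferon-induced Mx2 was at 7.6 ± 1.51 against 35.2 ± 12.6 CPM and Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, at 16.3 ± 3.13 against 42.2 ± 6.16 CPM. Hopx and the immediate early gene Egr1 had log2 fold changes of -1.37 and -1.11. Exons of Mx2, Hopx and Galnt15 overlap those of another gene, and reads were counted without regard to strand, so their counts are less certain. The smallest adjusted p of edgeR's quasi-likelihood test was 0.053. Of 17021 genes tested, 0 passed, 2531 had an unadjusted p under 0.05 where 851 are expected by chance, and DESeq2 called 268 (134 higher, 134 lower). Without the shallow sorafenib replicate 3 the edgeR count was again 0. It was 3 without water replicate 3, 1 without sorafenib replicate 2 and 2 without sorafenib replicate 4. It was 53 in a fit of all 4 groups and 82 without a filter on low counts.

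Of the lists at day 28, the VEGF response lay lower in 18 of 22 genes (median -0.62, camera adjusted p = 0.000365). Nrp2, Nrp1 and Aplnr, receptors of blood vessels, were at -1.47 ± 0.25 (SE), -1.35 ± 0.26 and -1.53 ± 0.29, and 6 members passed when adjusted over the list alone. The output of MAPK signalling had a median of -0.43 (adjusted p = 0.00777), with Spry4, Ccnd1, Dusp6 and Epha4 between -1.41 and -0.88. Immediate early genes lay lower in 20 of 21 (median -0.59, adjusted p = 1.1e-06), and 12 of them passed when adjusted over the list alone. Kinases that sorafenib inhibits had a median of -0.22 (0.0247), led by Ret at -1.31 ± 0.25 and Kdr, the main VEGF receptor, at -0.86 ± 0.21. Nuclear genes of oxidative phosphorylation lay lower in 45 of 45 (median -0.41, adjusted p = 1.1e-06), 0 of them past the threshold alone. That median was -0.207 without water replicate 4 and -0.227 without the shallow sorafenib replicate 3. By library, relative to the water mean, sorafenib replicate 4 was at -0.07, inside the water range of -0.27 to 0.33. Sorafenib replicates 2 and 3 were at -0.39 and -0.95. The estimated correlation between these genes was 0.94, so the shared direction of the 45 is not 45 separate observations. The interferon list lay lower in 32 of 35 (median -0.71, 1.18e-06) and the myeloid markers in 19 of 19 (median -0.58, 0.00874). Heat shock (-0.38), matrix (-0.39), fibroblast (-0.34), cell cycle (-0.36), atrial (-0.52), ion channel (-0.26), fatty acid oxidation (-0.31) and sarcomere (-0.23) lists also had lower medians, with adjusted p from 0.000365 to 0.0337. Relative to the water mean, the shallow replicate 3 was at -0.75 for the sarcomere, against -0.15 and 0.02 in the other sorafenib libraries. Those others lay inside the water range of -0.22 to 0.25. Replicate 3 was at -0.73 for fatty acid oxidation, against -0.19 and -0.01 and a water range of -0.17 to 0.30. For ion channels it was at -0.65, against -0.40 and -0.24 and a water range of -0.12 to 0.13. For heat shock it was at -0.83, against -0.43 and -0.10 and a water range of -0.195 to 0.206. For the matrix it was at 0.34, against -0.74 and -0.78, and for fibroblasts at -0.11, against -0.72 and -0.50. In the atrial list sorafenib replicate 4 was at -0.27, inside the water range of -0.30 to 0.37. For the myeloid markers the shallow replicate 3 was at -0.19, inside the water range of -0.23 to 0.35. The other sorafenib libraries were at -1.21 and -0.67. The circadian list had the higher median of 0.52 (adjusted p = 0.0131), with Ciart at 2.53 ± 0.47 and Dbp at 1.63 ± 0.32. Without sorafenib replicate 4, which was at 0.65 against 0.29 and 0.40 in the other sorafenib libraries, no list (0) was called higher. With an estimated correlation 0 of these 16 calls held (smallest adjusted p = 0.32). By fry, 3 passed: MAPK output (0.0059), VEGF response (0.0076) and immediate early genes (0.037). Of the 10 ways to part the 6 libraries, 2 gave 16 lists or more.

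The effects of both days were then averaged in a single fit of all 12 libraries, a comparison chosen after the day results had been seen. In it 801 of 18174 genes passed, 363 higher and 438 lower with sorafenib. Dyrk2, named at day 14, had the smallest p (log2 fold change -1.12 ± 0.12 (SE), edgeR adjusted p = 0.002). Spry4 was lower (-1.31 ± 0.15, 0.00403), as was Nox4 (-1.77 ± 0.23, 0.00632), and Fmo2 was higher (1.34 ± 0.19, 0.00779), each with all sorafenib libraries on one side of the water libraries at both days. In mRatBN7.2, Dyrk2 lies on chromosome 7 from 54348724 to 54381363, Spry4 on chromosome 18 from 30436513 to 30451426, Nox4 on chromosome 1 from 140900886 to 141078844 and Fmo2 on chromosome 13 from 75221149 to 75244377. The values are sums over the exons of each gene. Other genes named by size of fold were Zmynd12 (2.45), Fmo6 (2.09), Scgb1a1 (1.80), Cyp46a1 (1.47), Stkld1 (1.43), Ttll9 (1.42), Ankar (1.38), Galnt15 (1.36) and Mroh7 (1.35) on the higher side. On the lower side they were Prnd (-4.57), the endothelial gene Esm1 (-2.64), Vxn (-2.42), Rtl3 (-2.34), the nitric oxide synthase Nos2 (-2.02), Fcmr (-1.98), Pnpla3 (-1.89), P2ry6 (-1.81) and Cd83 (-1.67). Prnd had 0, 0 and 2 counts in the sorafenib libraries of day 28, so its fitted fold is not a measure of size. By summed counts its share at day 28 was 24.6 times as high with water (95% counting interval 6.63 to 206). In the sorafenib libraries of day 28, Vxn had 2, 1 and 2 counts, Esm1 4, 0 and 4, and P2ry6 8, 1 and 6. There Nos2 had 9, 1 and 6, Rtl3 13, 1 and 5, and Cd83 9, 1 and 21. On the higher side, counts per water library were 2 to 14 for Scgb1a1, 2 to 22 for Fmo6 and 6 to 16 for Zmynd12. They were 4 to 21 for Stkld1 and 8 to 15 for Cyp46a1. The fitted folds of all these genes thus also rest on few counts. The count of 801 depended on single libraries. It was 35 without sorafenib day 28 replicate 2, the library rich in mt-Rnr2, 60 without water day 14 replicate 3, and 1562 without sorafenib day 28 replicate 4. It lay between 180 and 510 without any one of water day 14 replicates 2 and 7, sorafenib day 14 replicates 5, 6 and 7, and water day 28 replicates 3 and 4. DESeq2 called 1765 genes. Stkld1 passed in 7 of 18 alternatives, and Spry4, Nox4 and Fmo2 in 18 of 18. Exons of Galnt15, Cyp46a1, Stkld1, Ankar and Nos2 overlap those of another gene.

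**Figure D1:**
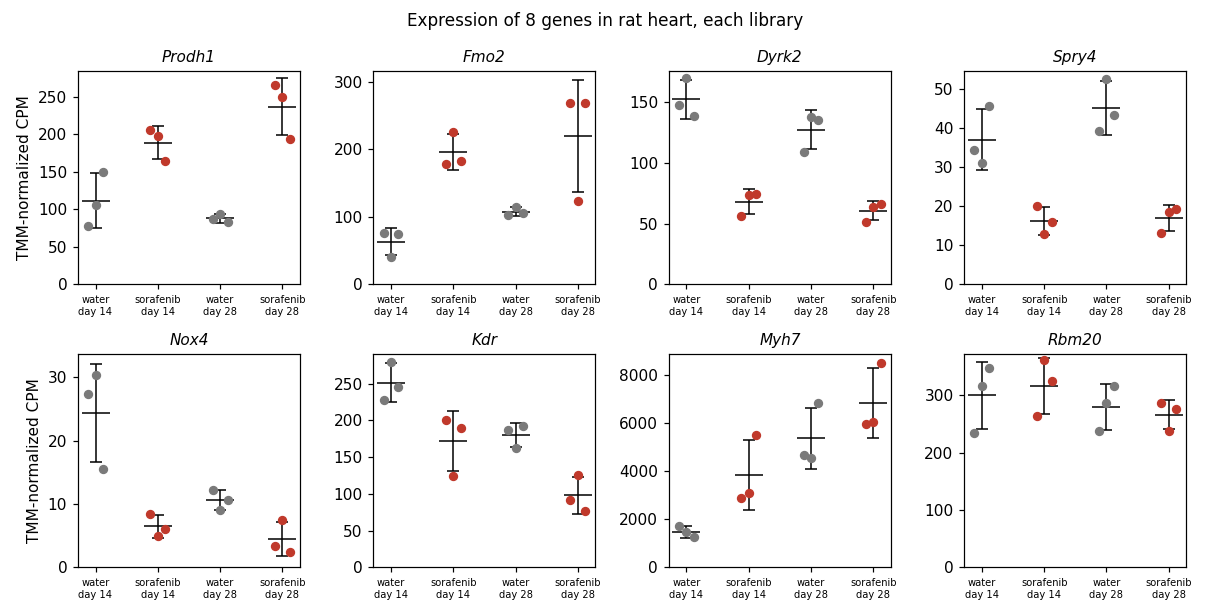
TMM-normalized CPM (y axis, linear from 0) of 8 genes in each of the 12 libraries (points), by treatment and day (x axis), with mean and SD as bars. Dyrk2 and Spry4 lie lower and Fmo2 higher in every sorafenib library than in every water library of the same day, while Rbm20 overlaps between the groups.

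**Figure D2:**
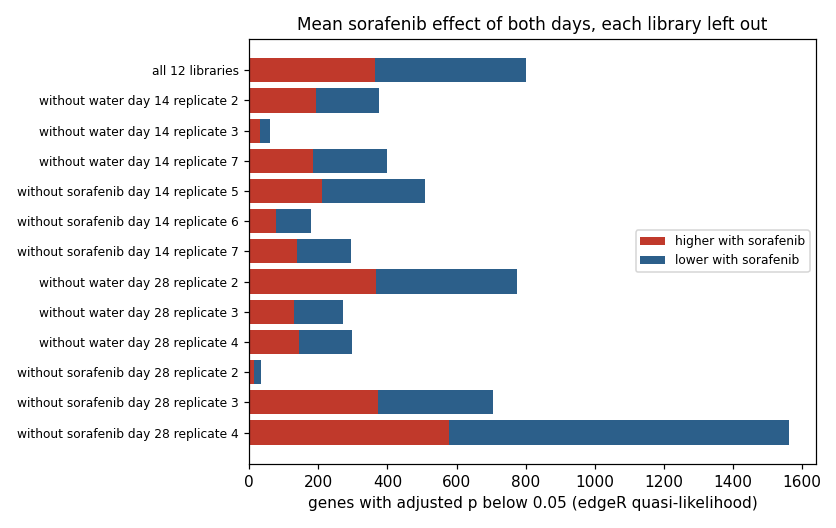
Number of genes past an adjusted p of 0.05 (x axis) for the mean sorafenib effect of both days, with all 12 libraries and without each in turn (y axis), split by direction. The count runs from 35 to 1562, against 801 with all libraries.

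In the averaged comparison, of the MAPK output list 3 of 16 fell over all genes, Spry4, Ccnd1 (-0.94 ± 0.17 (SE)) and Dusp6 (-0.83 ± 0.15), and adjusted over the list alone 9 fell and 1 rose. Of the VEGF response list 5 of 22 fell, among them Nrp2 (-1.34 ± 0.17), Nrp1 (-0.86 ± 0.16), Aplnr (-1.35 ± 0.26) and Apln (-1.03 ± 0.21), and adjusted over the list alone 10 fell and 1 rose. Of the target kinases 3 of 16 fell, over all genes and adjusted over the list alone: Ret (-1.01 ± 0.15), Kit (-1.08 ± 0.16) and Kdr (-0.73 ± 0.15). Kdr was at 172 ± 41.3 CPM against 251 ± 26.3 at day 14 and at 98 ± 25.5 against 180 ± 16.5 at day 28 (SD, n = 3 each). Flt1, the other main VEGF receptor, was at 0.13 ± 0.15, and endothelial markers as a list had a median of 0.06, with 3 of 23 that fell, Kdr, Emcn (-0.54 ± 0.13) and Cd34 (-0.70 ± 0.15). Camera gave an adjusted p of 0.0015 for MAPK output, 0.00565 for the VEGF response and 0.0112 for the targets. With an estimated correlation the adjusted p was 0.30, 0.45 and 0.30, and fry gave 0.0022, 0.0094 and 0.0034.

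Of 35 interferon genes 7 fell over all genes and 20 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 3.19e-09, adjusted p = 0.53 with an estimated correlation). Among them were Rsad2 (-1.05 ± 0.20 (SE)), Mx2 (-1.48 ± 0.29), Irf7 (-1.04 ± 0.22) and Rtp4 (-1.17 ± 0.26). Of 22 myeloid markers 3 fell, Cybb (-1.14 ± 0.27), C1qb (-0.98 ± 0.26) and C1qa (-1.23 ± 0.33), and 9 fell adjusted over the list alone (median -0.69, camera adjusted p = 0.000146, adjusted p = 0.60 with an estimated correlation). C1qa passed in 3 of 18 alternatives, C1qb in 5 and Cybb in 11. Relative to the mean of the water libraries of the same day, the mean of the myeloid list was between -1.24 and -0.15 in the 6 sorafenib libraries and between -0.34 and 0.53 in the 6 water libraries, so the ranges overlapped. The lists share 0 genes. Lymphocyte markers had a median of 0.06.

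Of 18 circadian genes 5 rose and 1 fell over all genes. Per2 (1.02 ± 0.19 (SE)), Per3 (1.11 ± 0.21) and Ciart (1.499 ± 0.30), repressors of the clock, were among those that rose, and the activator Clock fell (-0.49 ± 0.09). Adjusted over the list alone 7 rose and 2 fell (median 0.32, camera adjusted p = 0.033, adjusted p = 0.53 with an estimated correlation). The camera call was lost without sorafenib day 28 replicate 4 and without sorafenib day 14 replicate 7. Clock genes also differed between the water groups. Per3 was at 87.3 to 123 CPM in the water libraries of day 14 and at 12.1 to 38.6 CPM in those of day 28. Ciart was at 6.36 to 14 CPM and 1.61 to 3.83 CPM. The source of that difference was not tested. Of the immediate early genes 4 of 21 fell, Dusp1 (-0.61 ± 0.13), Btg2 (-0.57 ± 0.12), Egr1 (-1.58 ± 0.35) and Fos (-1.20 ± 0.29), and 12 adjusted over the list alone (camera adjusted p = 0.000146, adjusted p = 0.53 with an estimated correlation). At day 14 Egr1 was at 4.69, 8.14 and 26.3 CPM with water and 4.98, 1.84 and 2.79 with sorafenib. Fos was at 4.28, 5.7 and 12.5 CPM and 4.56, 1.03 and 2.67, so the ranges overlapped for both. These genes also differed between the water groups, with Egr1 at 72.5 to 83.6 CPM and Fos at 46.9 to 54.9 CPM in the water libraries of day 28. In the matrix list 3 of 32 fell, the basement membrane collagens Col4a1 (-0.64 ± 0.14) and Col4a2 (-0.58 ± 0.14) and the crosslinking enzyme Loxl2 (-0.69 ± 0.18), and 5 adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.75 with an estimated correlation). Heat shock genes lay lower in 16 of 16, with Hsph1 past the threshold (-0.60 ± 0.15), and cell cycle genes in 23 of 26, with Mcm3 (-0.89 ± 0.21). Camera gave 0.000216 and 0.000185 for these lists, and the adjusted p was 0.60 for both with an estimated correlation. Nuclear oxidative phosphorylation genes had a median of -0.17 with 0 past the threshold (camera adjusted p = 0.00416, adjusted p = 0.75 with an estimated correlation). In the atrial list (median -0.34, camera adjusted p = 0.0237, adjusted p = 0.30 with an estimated correlation), Dkk3 fell (-0.66 ± 0.18). So did Sln, which passed in 14 of 17 alternatives, with 7, 1, 5, 0, 0 and 0 counts in the sorafenib libraries against 62, 15, 14, 14, 93 and 18 with water. At day 28 it was at least 21.1-fold lower, taking 3 counts over the group as the floor, and at least 7.98-fold lower without water replicate 3, which held 93 of the 125 water counts. With Sln at that bound the list's median was again -0.34. Of 18 alternatives Loxl2 passed in 5, Dkk3 in 6, Fos in 7, Hsph1 in 9, and Egr1, Mcm3 and Col4a2 in 10. Of 100 regroupings of the 12 libraries, 33 gave 12 lists or more.

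**Figure D3:**
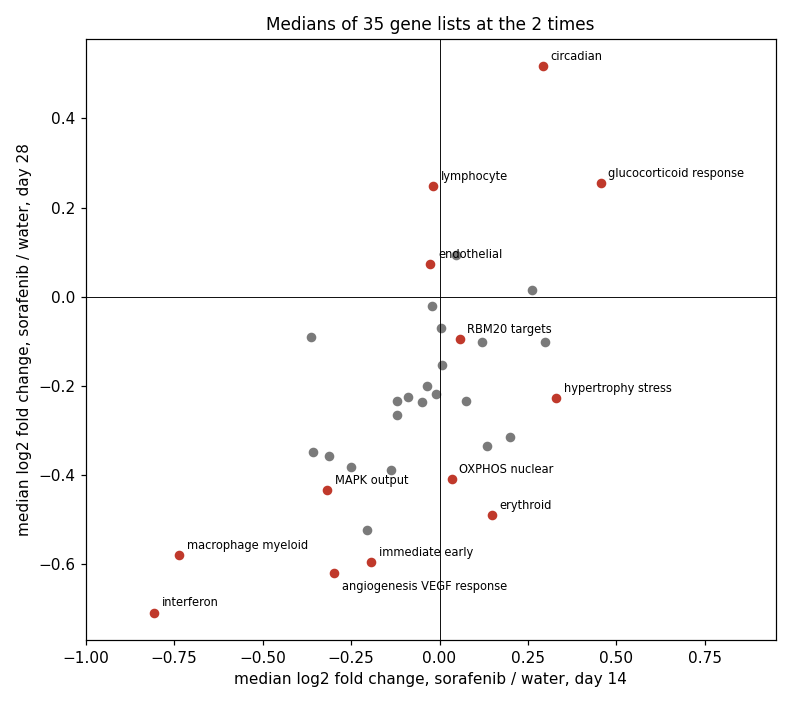
Median log2 fold change of sorafenib against water in 35 gene lists, day 14 (x axis) against day 28 (y axis), each point 1 list, with the named lists in red. Interferon and myeloid genes lie lowest at day 14 (-0.81 and -0.74), and the circadian list lies highest at day 28 (0.52).

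The gene of the splicing factor RBM20 did not pass the test at either day. Rbm20 was at log2 fold changes of 0.08 ± 0.19 (SE) at day 14, -0.03 ± 0.17 at day 28 and 0.00 ± 0.13 in the average (0.004816). Its exons overlap those of another locus. Its known splicing targets Ttn, Camk2d, Ldb3 and Ryr2 were at -0.16 ± 0.22, -0.13 ± 0.14, 0.13 ± 0.17 and -0.01 ± 0.18 in the average, none past the threshold. The values are sums per gene, so use of exons within a gene was not measured. Of 20 RBM20 target genes 1 fell in the average, and the list did not pass camera. Of the genes of the contractile and stressed myocardium, Myh7, the slow myosin heavy chain, rose in the average (0.86 ± 0.21, edgeR adjusted p = 0.0375), and passed in 11 of 18 alternatives, with adjusted p from 0.00016 to 0.0853. Its exons overlap those of other loci. Myh7 was at 1.38 ± 0.29 at day 14 and 0.39 ± 0.27 at day 28. Nppa, the atrial natriuretic peptide, was at 2.83 ± 0.69 at day 14 (adjusted p = 0.188) and 0.28 ± 0.92 at day 28, and Nppb at 1.08 ± 0.25 and -0.24 ± 0.36. Myh6, Col1a1 and Pdk4 were at -0.04 ± 0.22, -0.27 ± 0.30 and 0.04 ± 0.34 in the average. By edgeR over all genes none of Nppa, Nppb, Myh6, Col1a1 and Pdk4 passed at either day or in the average. DESeq2 called Nppa (adjusted p = 0.017) and Nppb (0.00344) at day 14, 1 of 13 alternatives for each, with adjusted p up to 0.431 and 0.415.

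Whether the effect differed between the days was tested directly, and no gene passed. The smallest p values belonged to Pgf, placental growth factor, whose difference of log2 fold changes (day 28 minus day 14) was -2.81 ± 0.54 (SE), and to Ngdn at 1.75 ± 0.34. Fabp4 and Rbp7, carriers of fatty acids and retinol, were at -1.14 ± 0.23 and -2.56 ± 0.52, and Cdo1 and C1qtnf7 at -2.63 ± 0.59 and -1.37 ± 0.32. On the other side Erich6, Slc33a1, Cpm and Ptger4 were at 2.77, 0.85, 1.86 and 0.80. Of 18174 genes, 0 passed edgeR's test, 803 had an unadjusted p under 0.05 where 909 are expected by chance, and DESeq2 called 5: Ngdn, Pgf, Fabp4, Rbp7 and a locus without a gene name. By camera 14 of 35 lists differed, and 0 with an estimated correlation (smallest adjusted p = 0.61). Without sorafenib day 28 replicate 4 the count was 7, and without water day 14 replicate 3 or sorafenib day 28 replicate 2 it was 9. Over 16641 genes tested at both days the log2 fold changes correlated with r = 0.457 (Spearman 0.502). The jackknife SE of r over libraries was 0.16, and r lay between 0.31 and 0.482 when single libraries were left out. Genes are not independent replicates. With no gene called at either day there was no overlap of calls to test by edgeR. Among genes with an unadjusted p under 0.05, 304 were higher at both days where 81.7 are expected from independent lists, 462 were lower where 94.1 are expected, and 9 had opposite signs. DESeq2 called 20 genes higher at both days where 1.83 are expected and 28 lower where 1.51 are expected (Fisher's exact test, p = 1.6e-15 and 6.2e-28). The days share no library.

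Between the water groups, 1191 genes were higher and 452 lower at day 28 than at day 14. By fold the higher ones were led by Dstnl1 (5.19), Hamp, which encodes hepcidin (4.45), Abra (3.64), Atp5me, a subunit of ATP synthase (3.29), and Fosb (3.15). The lower ones were led by Muc16 (-6.24), Upk1b (-6.08) and Msln (-5.73), which are genes of the mesothelium, and by the complement gene C4a (-3.29) and Gbp6 (-3.28). Muc16 was at 21.7 ± 17.6 CPM at day 14 and 0.282 ± 0.288 at day 28 (SD, n = 3 each), with 26, 649 and 601 counts in the water libraries of day 14. Upk1b had 1, 0 and 1 counts at day 28, so its fitted fold is not a measure of size. By summed counts its share was 94.1 times as high at day 14 (95% counting interval 25.6 to 784). Hamp had 4, 5 and 1 counts in the water libraries of day 14, so its fitted fold also rests on few counts. Dstnl1 passed in 4 of 12 alternatives, with log2 fold changes from 3.57 to 5.78 and 13, 249 and 563 counts in the water libraries of day 28. Muc16 passed in 6 of 13, Msln in 7 of 12 and C4a in 8 of 13, while Hamp, Abra, Atp5me, Fosb and Gbp6 passed in 13 of 13 and Upk1b in 12 of 12. The 2 days stand in separate tables, and time cannot be told apart from the table or the sequencing run. Among genes over 16 CPM, the log2 fold change fell with gene length (Spearman -0.41 over genes). DESeq2 called 2582 genes. Without water day 14 replicate 2 the edgeR count was 573, without water day 14 replicate 3 it was 385, and without water day 28 replicate 3 it was 651.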

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

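The bootstrap criterion behind the weighing (the interval over list members, from 10000 draws, must lie wholly beyond 0.5 of the pattern's median) and the tests of cell type markers were chosen after the values were seen. So were the share of a median kept without the length trend, drawn over the same genes before and after, the average of both days, as a comparison, and the removal of the trend with gene length, as an alternative. The test of differences between the days was planned. The bootstrap intervals cover the spread between list members and leave out the spread between libraries.

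By a test of the difference of effects (day 28 minus day 14, camera with a preset correlation), 14 lists differed, and 0 did with an estimated correlation (adjusted p = 0.61 to 0.76). Medians of the difference were -0.459 for nuclear oxidative phosphorylation (0.0347 at day 14, -0.409 at day 28), -0.511 for fatty acid oxidation (0.2 and -0.314) and -0.333 for the sarcomere (0.0753 and -0.233). They were -0.215 for RBM20 targets (0.0569 and -0.0954), -0.61 for myocardial stress (0.329 and -0.227), -0.307 for PPAR alpha targets (0.298 and -0.101) and -0.468 for the glucocorticoid response (0.456 and 0.255). For cell type lists they were -0.463 for fibroblasts (0.133 and -0.335), -0.545 for pericytes and smooth muscle (-0.0109 and -0.218) and -0.719 for erythroid genes (0.149 and -0.489). The VEGF response was at -0.298 (-0.298 and -0.62), immediate early genes at -0.204 (-0.194 and -0.594), autophagy and atrophy at -0.259 (0.119 and -0.102) and the circadian list at 0.283 (0.292 and 0.517). Of 100 regroupings of the 12 libraries 19 gave 14 lists or more (highest other 21), so chance is not excluded for the number of lists. For single genes the count was 0 in the real grouping, so all 100 regroupings had to give as many, which says nothing about chance. The highest, 801, came from the real grouping with the day 28 labels exchanged, which turns the difference into the average.

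The first pattern weighed is the lower level of nuclear oxidative phosphorylation genes at day 28 (median -0.409). With each library's trend with gene length removed the median was -0.349 (-0.396 to -0.313), or 85.4% of its size (79.9 to 103). The removed trend was fitted over all tested genes, where length and the day 28 log2 fold change had a Spearman correlation of 0.11. Among genes over 16 CPM the correlation was 0.32, and the short genes there had a median of -0.271. The removal may thus leave part of the trend in highly expressed genes, so it cannot decide on that cause. Without water replicate 4 it was -0.207 (-0.288 to -0.158), and without the shallow sorafenib replicate 3 it was -0.227 (-0.28 to -0.17). Both intervals reach across 0.5 of the median, so either library may carry much of the pattern and they cannot be told apart from an effect of sorafenib.

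The second is the lower level of interferon genes over both days (median -0.778). Leaving out the single library that moved it most, water day 14 replicate 2, left -0.571 (-0.778 to -0.441), which argues against 1 library as the whole cause. Myeloid markers had a median of -0.691 (-0.921 to -0.529), whose interval includes the median of the interferon genes, so a lower share of myeloid cells is a candidate explanation. An effect of sorafenib on interferon signalling within cells stays open and was not tested.

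The third is the lower level of MAPK output and VEGF response genes over both days (median -0.483). Endothelial markers had a median of 0.0576 (-0.148 to 0.126), which argues against a lower share of endothelial cells as the cause, though Kdr, Emcn and Cd34 fell. With the trend with gene length removed the median was -0.451 (-0.559 to -0.223). That interval over members reaches past 0.5 of the pattern's median, so the first criterion was not met. Over the same genes before and after, the median kept 93.4% of its size (87.9 to 104), and both lists passed camera (adjusted p = 0.00232 and 0.0123). The trend was fitted over all tested genes, where length and the averaged log2 fold change had a Spearman correlation of 0.026, so its removal could change little. Among genes over 16 CPM the correlation was 0.24, and the short genes there had a median of -0.151. The removal thus cannot decide on that cause. Before the removal, the adjusted p was 0.30 and 0.45 with an estimated correlation. An effect of kinase inhibition, which may lower these genes, stays open as a hypothesis, as do explanations not tested here.

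For the count of genes in the average, 1 of 100 regroupings, the real one, gave 801 or more, and the highest other gave 5. This argues against chance as its source, at this number of draws. The average was chosen after the day results had been seen, which the regroupings do not take into account. For its lists 33 of 100 gave 12 or more (highest other 21), so chance is not excluded. At day 14 all 10 splits gave as many genes as the real one (0, highest other 2), and 5 gave as many lists (12, highest other 20). At day 28 all 10 gave as many genes (0, highest other 0) and 2 as many lists (16, highest other 17). A real count of 0 fixes the outcome for genes in advance, so it says nothing about chance at either day. Between the water groups 1 of 10 splits, the real one, gave 1643 genes (highest other 0). Splits of 3 against 3 are too few for a share under 0.05.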

How the results depend on the processing

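Removal of the length trend and all alternatives for the average of both days were chosen after the data were seen. Over the named genes and the lists past camera, counted together under the alternatives, 4763 values kept direction and side of the threshold. Of the others 452 no longer passed, 172 newly passed and 52 changed direction. DESeq2 called 393 genes at day 14, 268 at day 28, 5 for the difference, 2582 between the water groups and 1765 in the average. Without a filter on low counts 87 passed at day 14 and 82 at day 28, and in the fit of all groups 4 and 53. With the length trend removed 5 passed at day 28. With the replicate block 108 passed at day 28 and 2171 between the water groups. The correlations of same-numbered libraries at day 28 were 0.1, 0.0081 and 0.19, so the numbers were not taken to pair libraries, and not every library correlated best with its own number. Leaving out single libraries gave 0 to 27 genes at day 14, 0 to 3 at day 28, 0 to 1 for the difference, 385 to 1703 between the water groups and 35 to 1562 in the average. Lists past camera numbered 2 to 17 at day 14 and 7 to 14 for the difference. With an estimated correlation 0 lists passed in each comparison, and fry gave 0 at day 14, 3 at day 28, 0 for the difference and 4 in the average. The cause of these shifts was not tested.

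Changes of sign occurred in genes that did not pass. With the length trend removed Ryr2 was at -0.0181 and Myh6 at 0.00716 at day 14, Flt1 at -0.0452 at day 28 and Rbm20 at -0.0821 in the average. In the average Ryr2 was at 0.00619 by DESeq2, 0.00833 with RLE factors and 0.0289 with the stricter filter, and Myh6 at 0.0031 with the stricter filter. Without single libraries the day 14 ranges were -0.0714 to 0.205 (Rbm20), -0.179 to 0.155 (Ttn), -0.162 to 0.111 (Camk2d), -0.0541 to 0.188 (Ldb3), -0.0833 to 0.273 (Ryr2) and -0.139 to 0.161 (Myh6). At day 28 they were -0.131 to 0.0612 (Rbm20), -0.135 to 0.0409 (Ryr2), -0.489 to 0.954 (Nppa), -0.523 to 0.1 (Nppb), -0.183 to 0.172 (Myh6), -0.0714 to 0.314 (Flt1) and -1.15 to 0.167 (Col1a1). In the average they were -0.0518 to 0.0848 (Rbm20), -0.0862 to 0.117 (Ryr2), -0.125 to 0.0898 (Myh6) and -0.16 to 0.363 (Pdk4). Depth limits the shallow library, where 1 count is 0.965 CPM.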

Other observations

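The genes in this paragraph were singled out after their values were seen, from lists that did not pass camera in the average of both days. Gja1, which encodes the main gap junction protein of the ventricle, fell by 1.165 (SE 0.202, edgeR adjusted p = 0.0148), 1 of 17 ion channel genes past the threshold. Among splicing regulators 2 of 32 rose, Clk4 (0.56 ± 0.10) and Srsf5 (0.45 ± 0.11). In the list of stress of the endoplasmic reticulum, 4 of 26 fell, among them Atf3 (-1.26 ± 0.25) and the chaperones Hsp90b1 (-0.61 ± 0.16) and Pdia4 (-0.59 ± 0.14), and Nupr1 rose (1.88 ± 0.36). Of the sarcomere list 2 of 30 rose, Myh7 and Tcap (0.84 ± 0.21). Rtn4 fell (-0.46 ± 0.12), the 1 RBM20 target of 20 past the threshold.

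Lists past camera in none of the 4 comparisons had these medians in the average. They were 0.04 for splicing regulators, -0.103 for calcium handling, -0.197 for glycolysis and hypoxia, -0.188 for mitochondrial biogenesis, 0.0576 for endothelium, 0.0588 for lymphocytes, -0.133 for adipocytes, 0.12 for skeletal muscle, -0.0883 for antioxidant genes and -0.0817 for apoptosis. The direction of the test and the sign of the median differed for calcium handling, endothelium, pericytes, lymphocytes and adipocytes at day 14, and for endothelium and skeletal muscle at day 28. They also differed for RBM20 targets and lymphocytes in the average, and for interferon, cell cycle and apoptosis in the difference.

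The mesothelial gene Muc16 was at 1.36, 33 and 32.6 CPM in the water libraries of day 14. In the sorafenib libraries it was at 12.7, 0.747 and 1.21 CPM at day 14 and 5.12, 0 and 10.4 CPM at day 28. Genes of ribosomal proteins, a list chosen after the data were seen, had a median log2 fold change of 0.985 between the water groups (73 genes), where time and table are confounded.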
